A study of Canis lupus familiaris with 8 samples.

How the data were processed

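RNA of peripheral blood mononuclear cells from 5 obese dogs and 3 normal dogs was sequenced. Per the labels' protocols, RNA was extracted with Trizol and 500 ng of total RNA went into each library, made with the Lexogen QuantSeq kit. QuantSeq primes at the poly(A) tail and sequences tags near it, so that a count stands for a transcript with little dependence on its length. The authors deposited 1 table per dog, with whole-number counts per gene symbol that were not normalized. Per the submitters' processing notes, Bowtie2 and bedtools were used. Their versions, their roles, the genome build, the annotation and the strand setting are not given in the sources used here. The tables of all 8 dogs listed the same 35048 genes in the same order. A symbol stood in more than 1 row for 411 rows, and the row with the highest mean kept the plain symbol. The symbols were looked up in a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, where 33411 were found. The table was used for names, gene spans and which genes overlap, and no coordinates are given. Genes without a characterised name were counted and not named.

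Genes that overlap or have near-identical sequences can share reads in these files. TMSB4X and an uncharacterised gene, with no overlap found in the reference annotation, had 160486 and 165003 counts in all (r = 0.997 over the libraries). How such reads were assigned is not given in the sources used here. The most abundant gene, which has no characterised name and is not in the reference table, took 3.11 to 20.6% of the counts of a library, with the highest share in obese dog 3. A group of 4 genes beside the globin genes HBM, HBQ1 and HBE1 took 8.09% of the counts of obese dog 3 and 0.0242 to 0.328% of those of the other obese dogs.

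Groups were taken from the labels, which also give the breed of each dog. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom between 2 libraries was 35.9. Library totals of 10264202 to 14910982 counts set the precision of single values. Intervals of counts are exact Poisson or binomial 95% intervals and cover counting error only, because no molecular identifiers were counted.

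The counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr by group (20632 genes kept), TMM scaling, and glmQLFit and glmQLFTest with robust estimation. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, at a threshold of 0.05. The common biological coefficient of variation was 0.54. Log2 fold changes are obese minus normal, and their standard error was computed as the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. The median log2 fold change of all genes was 0.09, and it was 0.08 with DESeq2 size factors and −0.03 with upper-quartile factors, so a shift of this size in a list is within the choice of scaling. FOXM1 was also tested with an exact two-sided permutation test on log2(CPM + 0.5) over all 56 splits.

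Before the data were examined, 17 gene lists and 11 lists of cell type markers were fixed, and each was tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were run beside it. With the preset correlation 15 lists passed, 8 of the gene lists and 7 of the cell type lists. With an estimated correlation camera passed 0 lists, 5 lists had an unadjusted p under 0.05 there, and fry passed 6. The estimated correlation was 0.157 for the FOXM1 and G2/M list and 0.646 for the platelet markers, well above the preset 0.01. Camera p-values with the preset correlation therefore overstate the evidence for such lists. Members were also adjusted over the list alone. The genes named were also fixed by rule: FOXM1, the 12 genes with the largest rise and the 12 with the largest fall among those with a characterised name, past the threshold with at least 5 CPM in a group and no overlap between groups, the 6 with the smallest p short of the threshold where a direction had fewer than 12, up to 4 members with the smallest p of each list that passed or had a member past the threshold, and 6 for the FOXM1 list. Members named as the exceptions of a list, members of lists that neither passed nor had a member past the threshold, and other genes named in the closing observations were chosen after their values were seen.

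The edgeR step was tested on simulated counts with the means and library sizes of these libraries, 19969 genes, of which 200 were changed singly and 40 together as a list. The test called 2% of genes changed 2-fold, 46% of those changed 4-fold, 90% of those changed 8-fold and 98% of those changed 16-fold, with 5 calls among 19729 unchanged genes. Genes were simulated independently of each other, so the simulation does not address tests of lists of correlated genes. Alternatives tried were DESeq2 1.42.0 size factors and upper-quartile factors, the DESeq2 Wald test, limma-voom with sample quality weights, no filter and a filter of 5 CPM in 3 libraries, removal of the erythroid markers, immunoglobulin segments and mitochondrial genes, each dog left out in turn, the dog number as a block, subsets by breed, and other thresholds. The removal left in the uncharacterised genes beside the globin genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.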

Results

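RNA was measured in peripheral blood mononuclear cells, the lymphocytes and monocytes separated from blood, of 8 dogs. The libraries were 3′ tag libraries, in which each transcript is counted from a read near its poly(A) end. The obese group held 5 dogs, which were a Dachshund (obese dog 1), a Chihuahua (obese dog 2), 2 Labrador retrievers (obese dogs 3 and 4) and a Welsh Corgi (obese dog 5). The normal group held 3 Beagles. The labels name each library as a separate dog, so the p-values below rest on the spread between dogs. Every normal dog was a Beagle and no obese dog was, so the effect of body condition and the effect of breed could not be separated in any comparison. Library totals ran from 10264202 counts in obese dog 1 to 14910982 counts in obese dog 5, and the normal dogs had 13118207, 10408203 and 14811053 counts. Expression is given as CPM, the counts scaled to a common library size, as mean ± SD with n = 5 obese and n = 3 normal dogs.

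The question set by the study was which genes differ in expression between obese and normal dogs, and its title names the transcription factor FOXM1. The lists of FOXM1 and G2/M genes, G1/S genes, plasma cell markers and mitochondrially encoded genes were lower in the obese dogs by camera, and each had an adjusted p = 0.144 with an estimated correlation. TNFRSF17, the receptor for B cell survival factors on plasma cells, had 0.647 ± 0.395 CPM in the obese and 14.1 ± 4.48 CPM in the normal dogs. FBP1, an enzyme of gluconeogenesis, had 4.66 ± 1.31 against 70.5 ± 31.1 CPM, and MAP3K8, a kinase downstream of Toll-like receptors, had 8.29 ± 2.40 against 74.4 ± 10.9 CPM. In the other direction, LTB, which encodes lymphotoxin beta, had 179 ± 42.5 CPM in the obese and 53.2 ± 12.3 CPM in the normal dogs. Of 20632 genes tested with edgeR's quasi-likelihood test, 10 rose and 38 fell at an adjusted p under 0.05, and in all 48 the 2 groups did not overlap. Over all genes tested, 2251 genes (10.9%) had groups without overlap, where chance gives 3.57%. These counts depended on single dogs. Without obese dog 3 there were 661 genes higher and 1023 lower, and all 48 genes were among them. Without obese dog 1, 2, 4 or 5 the counts were 0 and 2, 0 and 2, 0 and 3, and 3 and 12. Without normal dog 1, 2 or 3 they were 0 and 33, 0 and 20, and 0 and 2. At least 1735 genes had an unadjusted p under 0.05 in each of these fits, where chance gives a share of 0.05 of the 19969 to 21904 genes tested. FBP1 and MAP3K8 passed the threshold in all 8 fits that left out 1 dog, CENPF, DIAPH3 and ND6 in 4, and the other called genes taken by the naming rule in 1 to 3.

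Among the 12 genes with the largest decreases that had a characterised name and met the naming rule, CDC25A, a phosphatase that activates cyclin-dependent kinases, fell by 3.26 on the log2 scale (standard error 0.417, adjusted p = 0.0228, edgeR). NUF2, a kinetochore protein, fell by 3.04 (standard error 0.41, adjusted p = 0.0247), and CENPF, which also binds the kinetochore, fell by 2.62 (standard error 0.304, adjusted p = 0.0194). DTL, which directs replication factors to degradation, fell by 2.74 (standard error 0.407, adjusted p = 0.0373). TNFRSF17 had the largest decrease of the 12, 4.39 log2 units lower in the fit, and FBP1 fell by 3.92 (adjusted p = 0.00661, edgeR). EAF2, a transcription elongation factor, had 2.74 ± 1.73 CPM in the obese and 35.6 ± 16.3 CPM in the normal dogs. IRS1, the docking protein of the insulin receptor, had 1.02 ± 0.456 against 12.2 ± 4.74 CPM, a log2 fold change of −3.54 (standard error 0.468, adjusted p = 0.0245, edgeR). CCBE1, a secreted protein of lymphatic development, had 3.38 ± 1.77 against 38.3 ± 12.2 CPM. The remaining genes of the 12 were EMP1, with a log2 fold change of −2.70, and the formin DIAPH3, with −2.64. MAP3K8 fell by 3.16.

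Of the 10 genes that rose, 8 had a gene name. Among these DUSP28 and ANKMY1 had the largest values, with log2 fold changes of 2.75 and 2.52, but they overlap in the reference annotation and their counts moved together across the libraries (r = 0.997 over 8 libraries, descriptive), so their reads could not be told apart. OSBPL6, an oxysterol-binding protein, rose from 6.71 ± 1.74 CPM in the normal to 38.3 ± 7.64 CPM in the obese dogs, and MSRB3, a methionine sulfoxide reductase, from 7.30 ± 0.790 to 33.6 ± 6.43 CPM. SMAD7, an inhibitor of TGF-β signalling, rose by 2.02 log2 units (standard error 0.329, adjusted p = 0.0471, edgeR). MFHAS1 rose by 1.80, LTB by 1.75, and the polarity protein PATJ rose from 21.3 ± 1.16 CPM in the normal to 60.4 ± 9.34 CPM in the obese dogs. The next 6 named genes by p did not pass the threshold: MYO6, TP53I11, MLLT6, ZNF853, LIME1 and SLC25A40 had adjusted p-values from 0.0519 to 0.0673 (edgeR).

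**Figure D1:**
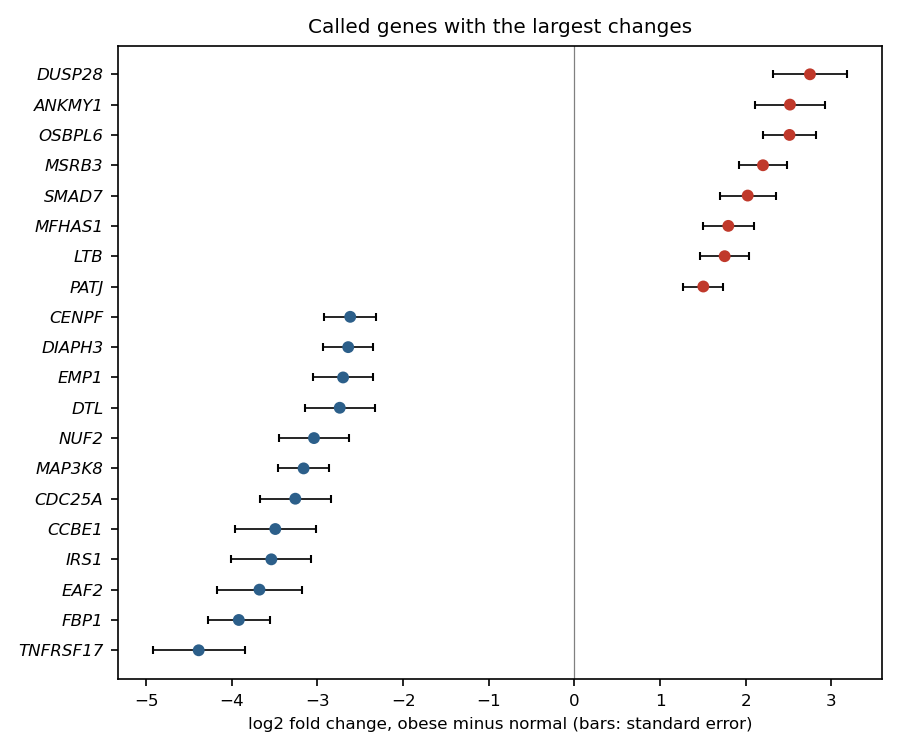
Log2 fold change, obese minus normal, of the 8 genes higher and 12 genes lower in obese dogs that the naming rule took at an adjusted p under 0.05; bars show the standard error of each edgeR estimate. Genes higher in the 5 obese dogs (red) lie above 0, up to 2.75 for DUSP28, and genes lower in them (blue) lie between −2.62 for CENPF and −4.39 for TNFRSF17.

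FOXM1, a transcription factor that drives genes of the G2 and M phases, was weakly expressed in both groups. The obese dogs had 2, 2, 25, 2 and 18 counts and the normal dogs 34, 5 and 52 counts. These correspond to 0.871 ± 1.16 CPM (SD, n = 5) and 2.09 ± 1.41 CPM (SD, n = 3). The log2 fold change of FOXM1 was −1.31 with a standard error of 1.02, and it did not pass the threshold (adjusted p = 0.568, edgeR). An exact two-sided permutation test over the 56 splits into 5 and 3 dogs gave p = 0.232, where the smallest possible p was 0.0179. Obese dog 3, at 2.84 CPM (95% Poisson interval 1.83 to 4.19, counting error only), lay within the range of the normal dogs. So did obese dog 5, at 1.05 CPM (0.622 to 1.66), above normal dog 2 at 0.553 CPM. Without obese dog 3 the log2 fold change of FOXM1 was −2.44 (adjusted p = 0.106, edgeR). In a limma-voom fit that weights the libraries by quality it was −3.11 and passed the threshold (adjusted p = 0.0272), and over all 19 alternatives the adjusted p ran from 0.0272 to 0.908. FOXM1 overlaps RHNO1 in the reference annotation, and whether strand was used in counting is not given in the sources used here, so reads of these 2 genes could not be told apart.

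Genes that act with FOXM1 in mitosis were lower in the obese dogs as a group. Of 39 measured members of the list of FOXM1 and G2/M genes, 38 had a negative fold change, the exception being CDC25B, and the median log2 fold change was −1.39. CENPF and CENPE, a kinetochore protein and a kinetochore motor, fell among all genes tested. Adjusted over the list alone, 22 members fell and none rose. TTK, a spindle checkpoint kinase, had 1.57 ± 0.661 CPM in the obese and 9.19 ± 2.41 CPM in the normal dogs, and CCNB2, the mitotic cyclin B2, had a log2 fold change of −2.62 (standard error 0.505). TPX2, a spindle assembly factor, had 9.50 ± 3.56 against 31.0 ± 4.84 CPM, and the centrosomal kinase NEK2 had 0.971 ± 0.418 against 5.68 ± 2.17 CPM. These 4 genes passed only when adjusted over the list alone, with the largest of those values at 0.00396 (edgeR). CCNB2 shares its locus with an uncharacterised gene whose counts moved with it. The list was lower by limma's camera test with the preset correlation (adjusted p = 1.68e-16) and by fry (adjusted p = 0.0083). With the estimated correlation between the genes, 0.157, camera gave an adjusted p = 0.144. The list mean was lower in each of the 5 obese dogs than in any normal dog.

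Genes of the G1/S transition and DNA replication followed the same direction. Of 32 measured members 30 had a negative fold change and the median was −1.03. None passed among all genes tested, and adjusted over the list alone 15 fell and 1 rose. MCM5, a subunit of the replicative helicase, had a log2 fold change of −1.95, and CCNE1, or cyclin E1, had 6.23 ± 3.15 CPM in the obese and 26.6 ± 7.48 CPM in the normal dogs. RRM1, of ribonucleotide reductase, had 34.2 ± 4.69 against 70.2 ± 3.48 CPM, and E2F8 had 1.66 ± 1.05 against 13.1 ± 6.48 CPM. Camera gave an adjusted p = 6.69e-10 for this list, fry 0.0194, and camera an adjusted p = 0.144 with an estimated correlation. In the same libraries the plasma cell markers had a median of −1.92 and the mitochondrially encoded genes a median of −1.75.

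**Figure D2:**
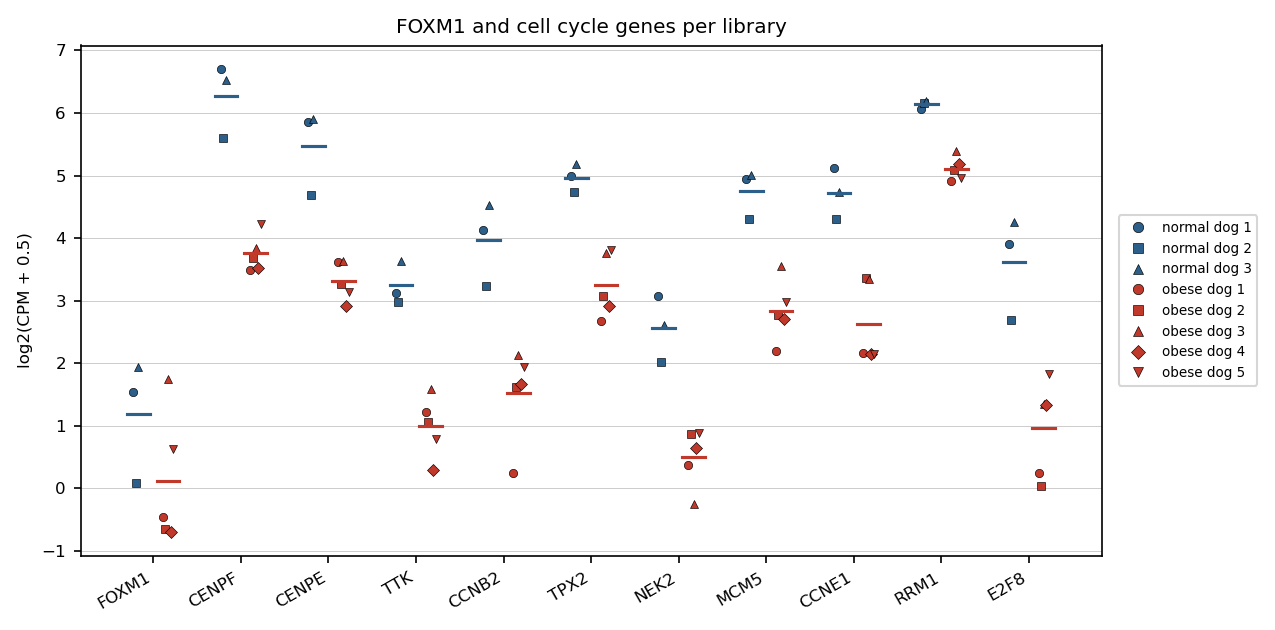
FOXM1 and 10 cell cycle genes in each library, as log2(CPM + 0.5); each point is 1 dog, with 5 obese dogs in red and 3 normal dogs in blue, and the short lines are group means. For each gene except FOXM1 all obese points lie below all normal points. These 10 genes had the smallest p of their lists in the same data, which favours separation. Some members not drawn, such as MKI67 and ASPM, overlapped between the groups. FOXM1 in obese dog 3 (2.84 CPM) lies between normal dog 1 (2.39 CPM) and normal dog 3 (3.32 CPM). FOXM1 in obese dog 5 (1.05 CPM) lies between normal dog 2 (0.553 CPM) and normal dog 1.

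Transcripts of the mitochondrial genome were lower in the obese dogs, and mRNAs of cytosolic ribosomal proteins were higher. The mitochondrially encoded genes took 1.79 ± 0.642% of all counts in the obese and 5.36 ± 0.849% in the normal libraries. All 13 had a negative fold change, with a median of −1.75. ND1, ND2, ND5 and ND6, which encode subunits of respiratory complex I, fell among all genes tested. Adjusted over the list alone, all 13 fell. ND6 had 891 ± 109 CPM in the obese and 4370 ± 539 CPM in the normal dogs (log2 fold change −2.29, standard error 0.238, adjusted p = 0.0115, edgeR). The list was lower by camera (adjusted p = 1.42e-14) and by fry (0.0083), with a camera adjusted p = 0.144 with an estimated correlation. Of 57 ribosomal protein genes, 55 had a positive fold change and the median was 0.55, but none passed, either among all genes or adjusted over the list alone. RPLP1 had 2334 ± 653 CPM in the obese and 1155 ± 187 CPM in the normal dogs, and the log2 fold changes of RPS21, RPS16 and RPS19 were 0.93, 0.81 and 1.15. The ribosomal list was higher by camera (adjusted p = 2.52e-09) and not past the threshold with an estimated correlation (adjusted p = 0.347) or by fry (adjusted p = 0.117). The ribosomal list means overlapped between the groups, with 8.21 to 8.81 log2 CPM in the obese and 7.51 to 8.47 in the normal dogs. The median of this list was 0.84 without normal dog 1 and 0.29 without normal dog 2. In the same libraries the T cell markers had a median of 1.29.

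Interferon-stimulated genes were lower in the obese dogs than in 2 of the 3 normal dogs. ISG15, a ubiquitin-like protein induced by interferon, had 1.57 to 6.58 CPM in the obese dogs and 3.16, 1578 and 375 CPM in normal dogs 1, 2 and 3. USP18 had 7.11 ± 1.95 CPM in the obese and 9.70, 181 and 92.0 CPM in the normal dogs, and EPSTI1 had 14.8 ± 5.71 against 267 ± 277 CPM. EIF2AK2, the kinase PKR, had 4.69 ± 2.21 against 28.0 ± 13.7 CPM, and its counts moved with those of an overlapping uncharacterised gene. The 32 measured members had a median log2 fold change of −2.51, and it was −1.37 without normal dog 2. None passed among all genes tested, and 25 fell adjusted over the list alone. The list mean of normal dog 1 lay within the range of the obese dogs. In normal dogs 1, 2 and 3 the list mean was 3.58, 6.96 and 5.73 log2 CPM, and the neutrophil marker mean was 3.47, 4.87 and 4.55. In obese dog 3 these means were 3.59 and 4.75. The list passed by camera (adjusted p = 5.81e-11), and had an adjusted p = 0.28 with an estimated correlation and 0.0998 by fry.

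Immediate-early genes, which respond within minutes to stimulation, were lower as a list, with a median of −0.56 over 27 members. Their mean was 6.64 log2 CPM in obese dog 3, 4.95 to 5.47 in the other obese dogs and 6.40 to 6.59 in the normal dogs, and the monocyte marker means of the same libraries were 5.30, 4.87 to 5.02 and 5.31 to 5.62. EGR1 had 46.7 ± 33.1 CPM in the obese and 758 ± 223 CPM in the normal dogs. It missed the threshold among all genes (adjusted p = 0.0519, edgeR) and was the 1 member that fell adjusted over the list alone. FOS had 82.4 ± 60.2 against 410 ± 98.1 CPM, DUSP1 had 41.4 ± 28.5 against 131 ± 45.8 CPM, and ATF3, which overlaps an uncharacterised gene whose counts moved with it, had 24.9 ± 20.5 against 60.0 ± 9.59 CPM, with the highest obese values of these 3 genes in dog 3. DUSP1 also overlaps an uncharacterised gene, with more counts than it had (10565 against 7568 over the libraries, r = 0.751). Camera gave an adjusted p = 6.78e-05, and an adjusted p = 0.28 with an estimated correlation, and fry gave 0.0997. The median was −1.08 without obese dog 3 and −0.37 without normal dog 1.

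Inflammatory cytokines and chemokines had a median of −0.78 over 21 members. In the same libraries the neutrophil markers had a median of −0.83. The monocyte marker means of the 2 groups did not overlap, but narrowly, with 5.304 log2 CPM in obese dog 3 and 5.305 in normal dog 2. The monocyte list did not pass by camera (adjusted p = 0.0598). Adjusted over the list alone, the inflammasome sensor NLRP3 and the cytokine OSM fell and TGFB1, which encodes an immunosuppressive cytokine, rose. NLRP3 had 69.1 ± 30.8 CPM in the obese and 201 ± 73.9 CPM in the normal dogs, OSM had 4.40 ± 3.19 against 18.2 ± 4.14 CPM, and TGFB1 had 38.3 ± 11.6 against 15.4 ± 1.05 CPM. IL1R2, the decoy receptor for IL-1, had 15.9 ± 23.3 against 254 ± 216 CPM and did not pass. Camera gave an adjusted p = 0.0104 for this list, and 0.28 with an estimated correlation, and fry gave 0.0998. The median of the list was −0.44 without normal dog 3. The unfolded protein response and heat shock list had a median of −0.30 over 33 members, with no member past the threshold, in libraries where the plasma cell markers had a median of −1.92. MANF had 44.4 ± 14.8 against 103 ± 37.9 CPM, HSP90B1 had 164 ± 62.2 against 350 ± 119 CPM, EIF2AK3 had 81.5 ± 16.7 against 140 ± 6.71 CPM and DNAJC3 had a log2 fold change of −0.68. Camera gave an adjusted p = 0.0104, which rose to 0.202 without normal dog 1, and an adjusted p = 0.28 with an estimated correlation. By fry the adjusted p was 0.0797.

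Among genes of metabolism, 2 members of the lists fixed in advance passed among all genes tested, and neither list passed as a whole. IRS1 fell in the list of insulin and adipokine signalling (32 members, median 0.28, adjusted p = 0.411 by camera), and SLC2A1, the glucose transporter GLUT1, rose adjusted over that list alone (adjusted p = 0.0458, edgeR) but did not pass in the glycolysis list (adjusted p = 0.0715), with 23.6 ± 3.19 CPM in the obese and 11.2 ± 2.87 CPM in the normal dogs. IGF1R had 109 ± 43.8 against 50.6 ± 13.3 CPM and PRKAA1 had 32.1 ± 8.21 against 18.1 ± 2.97 CPM, and neither passed. HADHB, of mitochondrial fatty acid oxidation, had 28.5 ± 5.47 against 74.5 ± 6.95 CPM (log2 fold change −1.38, standard error 0.231, adjusted p = 0.049, edgeR). PPARG had a log2 fold change of −1.18, ACACB had 4.84 ± 0.769 against 11.1 ± 2.23 CPM and FABP5 had 6.31 ± 5.40 against 17.7 ± 2.48 CPM, and none of these 3 passed. The list of fatty acid uptake, storage and oxidation (35 members, median −0.03) had an adjusted p = 0.0598 by camera. The lists of cholesterol synthesis and transport (median 0.38, adjusted p = 0.0797), oxidative phosphorylation encoded in the nucleus (median 0.06, adjusted p = 0.527) and glycolysis (median 0.20, adjusted p = 0.169) did not pass by camera either.

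**Figure D3:**
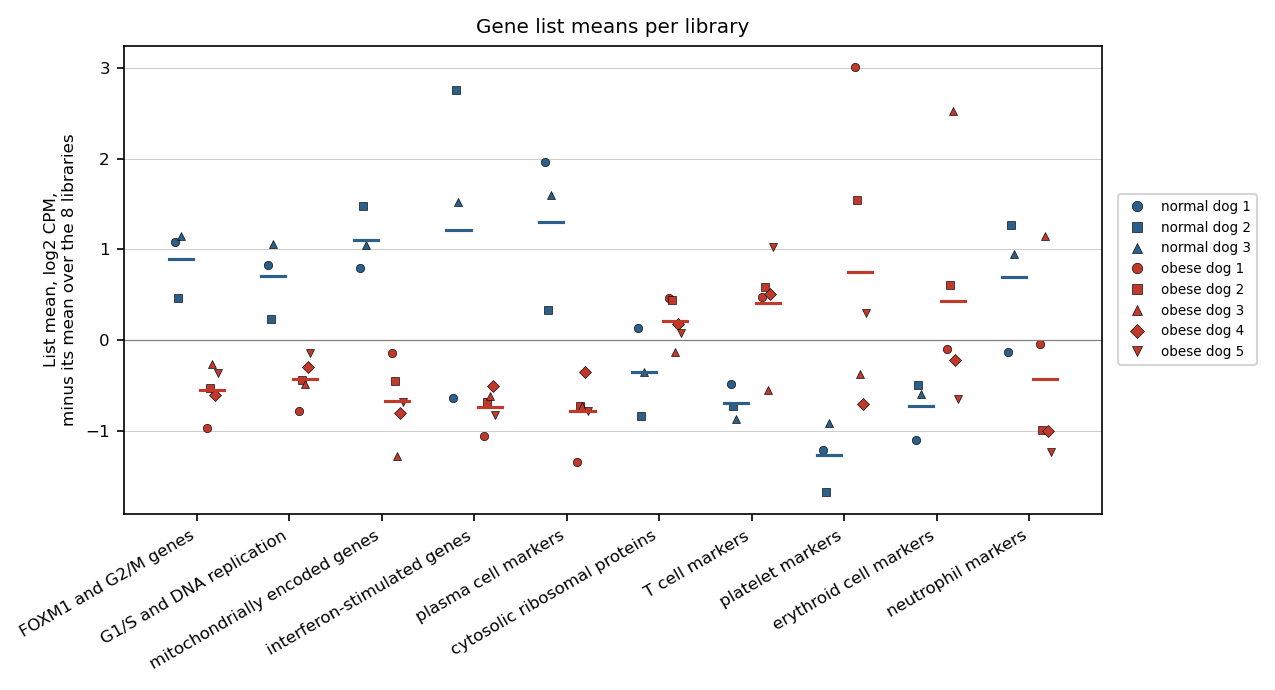
Mean log2 CPM of 10 gene lists in each library, minus the mean of that list over the 8 libraries; each point is 1 dog, with obese dogs in red and normal dogs in blue, and the short lines are group means. The groups do not overlap for the FOXM1 and G2/M, G1/S, mitochondrially encoded, plasma cell and platelet lists, normal dog 1 lies among the obese dogs for the interferon-stimulated genes, and obese dog 3 lies within the range of the normal dogs for the neutrophil and T cell markers, as does obese dog 1 for the neutrophil markers.

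Markers of cell types differed between the groups. Plasma cell markers were lower in the obese dogs, with all 10 measured members below 0 and a median of −1.92. TNFRSF17 fell among all genes tested and 8 members fell adjusted over the list alone. JCHAIN, the joining chain of secreted antibodies, had 23.2 ± 12.5 CPM in the obese and 355 ± 278 CPM in the normal dogs, TXNDC5 had 21.2 ± 9.06 against 107 ± 61.1 CPM, and the transcription factor IRF4 had 60.8 ± 20.6 against 167 ± 44.4 CPM. These markers passed by camera (adjusted p = 4.4e-07) and fry (0.0194), with a camera adjusted p = 0.144 with an estimated correlation. B cell markers did not pass (18 members, median 0.75, adjusted p = 0.296 by camera).

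T cell markers were higher in the obese dogs. Of 25 members 24 had a positive fold change, the exception being CD4, and the median was 1.29. None passed among all genes tested, and 19 rose adjusted over the list alone. IL7R, the interleukin-7 receptor, had 277 ± 104 CPM in the obese and 75.5 ± 25.4 CPM in the normal dogs, BCL11B had 181 ± 90.7 against 40.4 ± 11.4 CPM and LAT had 51.8 ± 23.2 against 16.5 ± 1.47 CPM. Obese dog 3 had the lowest T cell marker mean of the obese dogs, 5.08 log2 CPM, and the highest neutrophil and erythroid means, 4.75 and 4.50 log2 CPM. The T cell list passed by camera (adjusted p = 9.89e-11), but not with an estimated correlation (adjusted p = 0.28) or by fry (adjusted p = 0.0583). Cytotoxic and NK cell markers had a median of 0.79 over 21 members (camera adjusted p = 0.00338, 0.314 with an estimated correlation, fry 0.125). Adjusted over the list alone the chemokine CCL5 rose, with 61.0 ± 49.1 against 9.61 ± 5.62 CPM, and SH2D1B fell, with 49.8 ± 20.5 against 164 ± 90.6 CPM. CCL5 overlaps an uncharacterised gene with more counts than it had (8254 against 4382 over the libraries, r = 0.844). KLRD1 had 10.6 ± 9.11 against 1.62 ± 1.61 CPM and GZMK had 26.1 ± 17.4 against 9.69 ± 3.29 CPM, and neither passed. Regulatory T cell markers had a median of 0.97 over 6 members (camera adjusted p = 0.0137, 0.27 with an estimated correlation, fry 0.0486), and the adjusted p by camera was 0.111 without obese dog 2. FOXP3, the transcription factor of these cells, had 57 counts over the obese and 2 over the normal libraries, a ratio of CPM of 16.4 (exact 95% interval 4.33 to 138, counting error only), and rose adjusted over the list alone. IL2RA, which overlaps an uncharacterised gene whose counts moved with it, had 20.5 ± 20.5 against 4.67 ± 0.0441 CPM, TIGIT had 4.03 ± 0.915 against 2.03 ± 1.19 CPM and IKZF4 had 2.60 ± 1.12 against 1.35 ± 0.387 CPM.

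Transcripts of cells that a mononuclear preparation can carry over also differed. Platelet markers were higher in the obese dogs (18 members, median 3.54, camera adjusted p = 1.22e-05, 0.333 with an estimated correlation, fry 0.221). Adjusted over the list alone 13 rose and 1, SPARC, fell. The chemokine PPBP had 457, 222, 27.5, 25.4 and 69.3 CPM in obese dogs 1 to 5 and 5.59 ± 3.25 CPM in the normal dogs, F13A1 had 181 ± 104 against 22.8 ± 19.1 CPM, GP1BA had 29.9 ± 28.7 against 1.43 ± 0.909 CPM and SPARC had 1.26 ± 0.890 against 11.3 ± 7.76 CPM. Erythroid markers had a median of 1.10 over 18 members and no member past the threshold (camera adjusted p = 0.0252, 0.437 with an estimated correlation, fry 0.333). The call ended without obese dog 3 (median 0.49, adjusted p = 0.231), obese dog 2 (adjusted p = 0.0865) or normal dog 1 (adjusted p = 0.115, camera), and with AHSP at its bound the median remained 1.10. AHSP, the chaperone of alpha globin, had 284 CPM in obese dog 3 and 2.27 to 5.22 CPM in the other obese dogs. With 0 counts in the normal dogs, it was at least 525-fold higher over the obese group, against a floor of 3 counts over the normal group, and at least 52.3-fold higher without obese dog 3. HEMGN had 242 counts over the obese and 1 over the normal libraries, a ratio of CPM of 139 (exact 95% interval 24.7 to 5509), and without obese dog 3 it had 40 counts over the obese libraries and a ratio of 26.4 (4.47 to 1068). GATA1 had 5.53 ± 4.46 against 0.563 ± 0.857 CPM and GYPC 42.5 ± 15.0 against 22.1 ± 3.52 CPM. Neutrophil markers had a median of −0.83 over 22 members (camera adjusted p = 0.00577, 0.391 with an estimated correlation, fry 0.276). LCN2 fell adjusted over the list alone, with 10.8 ± 4.92 against 32.5 ± 7.13 CPM. ITGAM had 78.5 ± 43.4 against 159 ± 57.6 CPM, CAMP had 36.5 ± 50.8 against 8.39 ± 5.30 CPM and MMP8 had 2.38 ± 2.89 against 6.36 ± 3.64 CPM. The median of the neutrophil list was −1.41 without obese dog 3 and −0.34, with an adjusted p of 0.0746 by camera, without normal dog 2.

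Breed differed among the obese dogs and was not tested, since 3 breeds had 1 dog each. With the 3 obese dogs that were not Labrador retrievers against the 3 normal dogs, 558 genes were higher and 741 lower, and all 48 genes were among them. With the 2 Labrador retrievers alone against the normal dogs, edgeR called 0 genes at an adjusted p under 0.05. Of 20833 genes tested there, 1987 had an unadjusted p under 0.05, where chance gives a share of 0.05. The 2 Labrador retrievers differed from each other, with mitochondrially encoded genes at 0.690% of counts in obese dog 3 and 2.00% in obese dog 4, and T cell marker means of 5.08 and 6.13 log2 CPM. All 48 called genes kept their direction in both of these fits. This was fixed in advance, because in all 48 no obese dog overlapped the normal dogs.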

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

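The correction for gene span, the count of obese Beagles and the test of scaling, which replaced one with scalings that moved too little to decide, were chosen after the results were seen, the plasma cell markers had been seen before the immunoglobulin counts were summed, and the decision on olfactory receptor counts was tightened to their spread after the value was seen.

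Single obese dogs stood apart from the other 4 in 7 of 127 values tested, where chance alone gives about 6.35, and 5 of the 7 were in obese dog 3. FBP1 had 2.45 CPM in obese dog 5 and 4.76 to 5.86 CPM in the others. CCNB2 had 0.681 CPM in obese dog 1 and 2.58 to 3.86 CPM in the others. In obese dog 3, SLC25A40 had 20.3 CPM (others 32.6 to 36.6), ATF3 had 61.5 CPM (others 13.5 to 18.5), IKZF4 had 0.680 CPM (others 2.58 to 3.44) and AHSP had 284 CPM (others 2.27 to 5.22). The genes beside the globin genes took 8.09% of the counts of obese dog 3 and 0.0242 to 0.328% of those of the others.

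The 8 libraries can be split into 5 and 3 in 56 ways. For the number of genes higher in obese dogs, 2 splits, the real one included, gave a count as large as the real 10, with 21 as the highest other. This is under 0.05 of the splits before any adjustment over the counts tested, which does not exclude chance. That count of 10 fell to 0 without obese dog 1, 2 or 4 or any normal dog. For the genes lower in obese dogs, 3 splits gave as many as the real 38, with 196 as the highest other, so chance was not excluded. For the gene lists past the threshold, 5 splits gave as many as the real 8, with 10 as the highest other, so chance was not excluded. Most other splits also passed gene lists by camera with the preset correlation, so a pass there is not particular to the real groups. For the cell type marker lists past the threshold, 1 split, the real one, gave 7, with 6 as the highest other. This is also under 0.05 of the splits, but the counts were not adjusted for one another, so chance was not excluded here either. That count of 7 was 5 without obese dog 2 and 0 by camera with an estimated correlation. The split of obese dog 3 with normal dogs 2 and 3 against the rest gave 21 genes higher and 196 lower, and the lower count, several times the real 38, points to a structure of the samples that the groups do not give.

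The cell cycle gene lists were lower in the obese dogs. The tables argue against a trend with gene span as the whole cause. Over all genes the median log2 fold change ran only from 0.27 among the shortest spans to −0.11 among the longest. Correcting for this trend could therefore move a list only little. The median of the FOXM1 and G2/M list was −1.34 after it (bootstrap interval −1.64 to −1.008), against −1.39 before. Transcript length was not tested. Fewer plasma cells may contribute and stay open, since summed immunoglobulin counts were 3.24 times higher in the normal dogs, 4705 ± 2307 against 1452 ± 434 CPM, without overlap. Breed cannot be told apart from body condition, because the series holds 0 obese Beagles. Body condition, which the design names, stays open as untested against these.

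The mitochondrially encoded genes were lower in the obese dogs. The tables argue against scaling of the libraries, since a factor per library moves all genes alike and the median of the list lay at −1.84 relative to the median of all genes (bootstrap interval over its genes −2.17 to −1.57). DNA carried over into the normal libraries cannot be told apart from a change in transcripts: olfactory receptor counts were 1.17 times higher in the normal dogs, under the bound of 1.2 set beforehand, but leaving out 1 dog gave ratios from 1.011 to 2.12, the highest without obese dog 3. Body condition and breed stay open here as well.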

How the results depend on the processing

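The correction for gene span and the removal of obese dogs 1 and 3 together were chosen after seeing the data, and the other alternatives were planned.

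No result reversed. Of 1830 values of named genes under the alternatives, 1360 kept their side of the threshold, 206 lost and 264 gained it, and of 297 values of lists, 278 kept it and 19 lost it, not counting camera with an estimated correlation and fry, where 0 and 6 of all 28 lists passed. Genes higher in obese dogs and genes lower in obese dogs numbered 10 and 38 as reported, and 599 and 428 with the DESeq2 Wald test, 1881 and 2043 with voom and sample weights (FOXM1 −3.11), and 16 and 63 with at least 5 CPM in 3 libraries, where FOXM1 was filtered out and gave no value. Of the 48 genes, 47 were shared with the Wald test and 48 with voom. With the erythroid markers, immunoglobulin segments and mitochondrial genes removed, 5 were higher. The uncharacterised genes beside the globin genes, abundant in obese dog 3, were not removed in that fit. Without the Labrador retrievers the counts were 558 and 741, with only the Labrador retrievers among the obese 0 and 0 (1987 genes at an unadjusted p under 0.05, edgeR), and with obese dogs 1 and 3 left out 815 and 1158. An unadjusted p under 0.05 with a 2-fold change gave 1202 and 1013, an adjusted p under 0.1 gave 71 and 134, and a test against a 1.5-fold change gave 2 and 13. For these the cause was not tested, beyond the fewer dogs or the other threshold.

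Leaving out 1 dog gave 0 to 661 genes higher and 2 to 1023 lower, 7 to 9 gene lists, 5 to 8 cell type lists, and −2.44 to −0.83 for FOXM1. Camera with an estimated correlation passed 0 gene lists and 0 cell type lists, and fry passed 3 and 3. With the dog number as a block edgeR called 0 higher and 0 lower (1634 of 20632 genes at an unadjusted p under 0.05, where chance gives 1032). In that fit the inflammatory, unfolded protein response and neutrophil list calls ended (camera adjusted p 0.149, 0.149 and 0.109). These calls also ended with only the Labrador retrievers (0.0521, 0.136 and 0.148), as did the regulatory T cell call (0.38), which ended too without the Labrador retrievers (0.0591), obese dog 2 (0.111) or obese dogs 1 and 3 (0.0606). The erythroid call ended with voom (0.343), at least 5 CPM in 3 libraries (0.36), without the Labrador retrievers (0.144) or obese dogs 1 and 3 (0.251), and without obese dog 2 or 3 or normal dog 1. The numbers name different dogs, and deviations of dogs with the same number correlated across genes at −0.0289, −0.209 and 0.00545, so the numbers do not pair them. Quantile normalization and another pseudocount were planned for normalized values and did not apply to counts. In simulated counts of this depth 2% of 2-fold changes were called, so few changes of that size would be called.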

Other observations

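The test of CD4 against neutrophil markers was chosen after the result was seen, as were the genes named in this part.

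Other genes that fell in the obese dogs at an adjusted p under 0.05 (edgeR) were picked singly from those past the threshold. NDC80 and SPC24, kinetochore proteins, had 8.69 ± 3.37 and 1.69 ± 0.369 CPM in the obese and 50.2 ± 20.4 and 9.95 ± 2.08 CPM in the normal dogs, and NDC80 overlaps an uncharacterised gene whose counts moved with it. SMC2, of condensin, had 8.74 ± 2.33 against 50.1 ± 20.8 CPM, and LMNB1, lamin B1, had 110 ± 21.2 against 350 ± 98.5 CPM. HAVCR1, or TIM-1, had 21.7 ± 6.46 against 89.4 ± 8.13 CPM. UGCG, which makes glucosylceramide, had 138 ± 40.4 against 540 ± 135 CPM.

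Other lists did not pass by camera. Among apoptosis regulators (29 members, median −0.05, adjusted p = 0.169), the anti-apoptotic gene BCL2 rose and CASP8, MCL1 and BCL2L1 fell adjusted over the list alone. BCL2 had 344 ± 164 CPM in the obese and 88.3 ± 19.2 CPM in the normal dogs, and CASP8 had 12.3 ± 5.49 against 49.8 ± 17.6 CPM. The p53 targets (23 members, median 0.01, adjusted p = 0.827) and the NF-kB pathway (27 members, adjusted p = 0.347) had no member past the threshold, and the median of the NF-kB list was 0.03 while its mean was −0.15 and its camera direction down. Of 25 antioxidant and NRF2 genes (adjusted p = 0.814) GPX1 rose and TXN fell adjusted over the list alone, with a median of 0.03 and a camera direction of down. Among dendritic cell markers (13 members, median 0.48, adjusted p = 0.0801) ZBTB46, IRF8, FCER1A and CCR7 rose adjusted over the list alone, and CCR7 is also in the T cell list. Monocyte markers (21 members, median −0.15) had an adjusted p = 0.0598 by camera and 0.0323 by fry, and MSR1, VCAN and TLR4 fell adjusted over the list alone. Of the 18 B cell markers POU2AF1 fell adjusted over the list alone, with a log2 fold change of −2.55. The eosinophil, basophil and mast cell markers (8 members, median 0.35) had an adjusted p = 0.625.

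CD4 was the only T cell marker with a negative fold change, and it had 586 CPM in obese dog 3, 29.9 to 51.2 CPM in the other obese dogs and 114, 363 and 459 CPM in the normal dogs. A candidate explanation is granulocytes in the preparation, since neutrophils of dogs carry CD4. Over the 8 libraries CD4 and the neutrophil marker mean had Spearman rho = 0.595 (exact permutation p = 0.132, adjusted 0.132) and Pearson r = 0.894 (exact permutation p = 0.0104, adjusted 0.0119), in a family of 2 relations, and r was 0.799 without normal dog 2 and obese dog 3. With the other T cell markers CD4 had rho = −0.714 (p = 0.0576, adjusted 0.115, exact permutation) and r = −0.905 (exact permutation p = 0.0119, adjusted 0.0119), and r was −0.944 without obese dog 5 and normal dog 3. The neutrophil marker CSF3R had 423 CPM in obese dog 3, 25.1 to 34.5 CPM in the other obese dogs and 140, 362 and 293 CPM in normal dogs 1, 2 and 3. CD3E, a T cell marker, had 49.2 to 56.7 CPM in obese dog 3 and the normal dogs and 107 to 179 CPM in the other obese dogs. A change in T cell numbers alone would move CD4 with the other T cell markers. The opposite relation argues against that for the difference between obese dog 3 with the normal dogs and the other obese dogs. It did not hold among obese dogs 1, 2, 4 and 5. There CD4 and the mean of the other T cell markers were both lowest in dog 1 and both highest in dog 5. Granulocytes cannot be told apart from other changes in T cells, since the rank correlations did not pass, both Pearson correlations did, and the libraries were few.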
